A study of Homo sapiens with 6 samples.

How the data were processed

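RNA-seq was done on 6 samples of MKN28 cells, 3 with an empty vector and 3 with short hairpin RNA against VPS35. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into libraries by Illumina protocols. Whether poly(A) selection, ribosomal RNA depletion or a strand-specific kit was used is not given in the sources used here. The submitters' processing notes name fastp, HISAT and RSEM and the genome build GRCh38.p13. Their versions, their roles and the annotation release are not given in the sources used here. Sample groups were taken from the sample titles, and the columns were matched to samples by name.

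The authors' deposited table holds, per gene, an expression signal for each sample with 2 decimals. Its header names no unit, and TPM and FPKM cannot be told apart from a table of part of the genes, so the signal was used as deposited and taken as comparable between samples. The mean columns of the authors equal the means of the 3 samples within rounding. Fold changes of shVPS35 over vector are the authors' deposited ratio, and the log2 fold changes are the log2 of that ratio, per the file headers. The p-value and adjusted p-value of each gene are also the authors', and the test behind them is not given in the sources used here. All 426 genes have an adjusted p below 0.05 and an absolute log2 fold change above 1, with a largest adjusted p of 0.0497 and a smallest absolute log2 fold change of 1.00 in the authors' deposited table. The number of genes tested was recovered from the p-values and adjusted p-values, since a Benjamini-Hochberg adjusted p equals p times the number of genes over the rank. With 16063 genes, 387 of the 422 genes with a nonzero adjusted p had a whole-number rank within 0.01, and 4 genes had a p of 0. Read depth is unknown, so no counting interval can be given. Precision was judged from the replicates. In the 80 genes with both group means of 5 or more, the median coefficient of variation was 5.53% in the vector and 6.41% in the shVPS35 samples. Pearson's r across genes was 0.983 to 0.987 between samples of a group and 0.794 to 0.813 between groups, over genes chosen for differing between the groups and not independent of each other. Any pair of samples had the same value, to the 2 decimals given, in at most 12 of the 426 genes.

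Expression values were tested on the log2(value + 1) scale with limma 3.58.1 (trend and robust variance estimates, statmod 1.5.0, R 4.3.3) for listed genes with a value of 1 or more in at least 3 samples, with group as the only term. Fold changes on this scale understate the change of low genes. Adjusted p-values follow Benjamini and Hochberg over the 292 genes tested, and the threshold was 0.05. Count-based tests did not apply to these values. Values were simulated for this comparison, with 303 genes run and folds set on value + 1. The test recovered 93.8% of 80 genes changed by a fold of 2 and 98.7% of 77 changed by a fold of 4. It called 2.74% of 146 unchanged genes. In low genes these folds are larger changes of the value itself, so recovery of such folds of the value is overstated there. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Positions and gene types come from GENCODE 29 on GRCh38, which shares its primary assembly with the authors' build, and 421 of 426 gene identifiers matched.

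The named genes followed a rule fixed before the data were examined. VPS35 came first. The 10 genes that rose most and the 10 that fell most by limma log2 difference followed, among genes past the threshold whose groups did not overlap and whose higher group mean was at least 5. From each gene list with 2 or more listed members, up to 4 with the smallest adjusted p were taken, and then the 5 genes with the highest mean level. Remaining members of the lists are named where their count is given, except for members that are not reported here. The 19 gene lists, also fixed then, cover retromer and sorting nexins, retromer cargoes, lysosome and autophagy, YAP and TAZ targets, integrins and focal adhesion, IL6, JAK and STAT3 signalling, NF-kB targets, interferon-stimulated genes, cell cycle, epithelial to mesenchymal transition, cholesterol synthesis, unfolded protein response and ATF4, p53 targets, MAPK feedback and immediate early genes, hypoxia and glycolysis, Wnt targets, gastric and intestinal markers, markers of other cell types, and histones. For each list with 2 or more listed members, the share that rose was compared with the 44.6% of all listed genes by a 2-sided exact binomial test, adjusted over the 10 such lists. A 1-sided hypergeometric test of the number listed, adjusted over 19 lists, was added after the data were seen. It used all 16063 genes tested as background, or 10000, and took every list member as tested. Counts in each list were also adjusted over the list alone.

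Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5, centring on the median gene, trimmed-mean scaling factors, the replicate number as a block, leaving out each sample in turn, a log2 limit of 1 and a stricter adjusted p of 0.01. Genes that are not in the table, exons and isoforms were not analysed here.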

Results

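RNA was sequenced from MKN28 cells, a human gastric cancer line that cell line registries list as a derivative of MKN74, carrying either an empty vector or short hairpin RNA against VPS35 (shVPS35). VPS35 is the core subunit of retromer, the complex that returns membrane proteins from endosomes to the trans-Golgi network and the plasma membrane. Each group held 3 samples, which the series' design text calls biological replicates, without saying whether the shVPS35 samples share a hairpin or a clone. The comparison asks which transcripts differ when VPS35 is depleted. The values are the expression values per gene and sample in the authors' deposited table, whose header names no unit, for the 426 genes that the table lists as changed. Sequencing depth is unknown, since these values carry no read counts. Over the listed genes the values summed to 5130, 5078 and 5029 in the vector samples and to 4853, 5004 and 4696 in the shVPS35 samples.

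VPS35 itself (ENSG00000069329; GRCh38, chromosome 16, 46656132 to 46689518, minus strand) was read first as a check on the labels. Its expression value was 64.4, 64.3 and 67.2 in the vector samples and 12.9, 15.6 and 11.8 in the shVPS35 samples. The mean fell from 65.3 ± 1.67 to 13.4 ± 1.97 (SD, n = 3 per group), so that 20.6% of the vector level was left. On the log2(value + 1) scale the difference was -2.21 ± 0.09 (SE; limma adjusted p = 1.8e-07). Of the 19 genes on the list of retromer subunits and sorting nexins, VPS35 was the only listed member.

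With VPS35 depleted, more of the listed genes fell than rose. SPINK6, TGFBI, SERPINE2, F3 and CCND1 were among the transcripts that fell, and MAMDC2, RHOU, MRC2, HPD and the RNA AL355075.4 among those that rose. All 10 listed members of a list of MAPK feedback and immediate early genes fell, as did all 7 listed members of a list of NF-kB target genes. No receptor or transporter from the list of retromer cargoes was in the table.

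The authors' deposited table lists 236 genes that fell and 190 that rose, each with an adjusted p below 0.05 and an absolute log2 fold change above 1. From the p-values and adjusted p-values in the authors' deposited table, 16063 genes had been tested, so that the listed genes made up 2.65% of them. The last listed gene had rank 4255 by p, and 10.0% of the genes up to that rank were listed. Among the 100 smallest p-values in the authors' deposited table's ranking, 53 genes were listed, of which 34 fell and 19 rose. Among the 500 smallest, 66 fell and 51 rose, and among the 1000 smallest 85 fell and 85 rose. The median log2 fold change in the authors' deposited table was -1.55 for genes that fell and 1.5 for genes that rose. Among genes with annotation, 202 of the 233 that fell and 164 of the 188 that rose were protein coding. A higher group mean of 50 or more was found for 17 genes that fell and 7 that rose, and one below 1 for 61 that fell and 49 that rose. For 398 of the 426 genes all 3 samples of one group lay above the 3 of the other, a separation that chance gives for 10% of genes that were not selected. These genes were listed because they differed between the same 6 samples, so a high share follows from their selection.

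**Figure D1:**
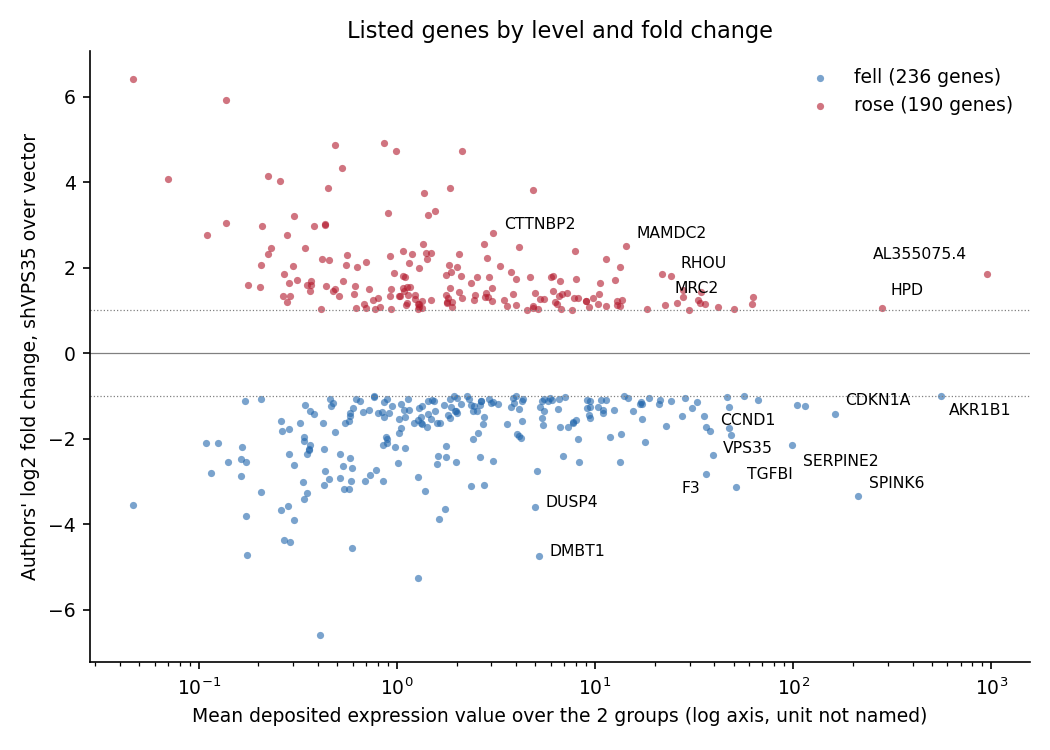
Each point is a gene of the authors' deposited table, placed by its mean expression value over both groups (log axis, unit not named) and by the authors' log2 fold change of shVPS35 over vector, with dotted lines at the limits of 1 and -1. The 236 genes that fell are blue and the 190 that rose are red, and AL355075.4 lies farthest to the right.

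Among the genes with a higher group mean of at least 5, those that fell most on the log2(value + 1) scale were led by SPINK6, DMBT1 and TGFBI. The order depends on the pseudocount. With 0.1 the log2 differences of DMBT1 (-4.58) and DUSP4 (-3.42) were larger in size than those of SPINK6 (-3.27) and TGFBI (-3.11). SPINK6, a secreted inhibitor of kallikrein proteases (chromosome 5, 148202794 to 148215137, plus strand), fell from 385 ± 9.13 to 40.2 ± 5.71 (SD, n = 3 per group), a difference of -3.24 ± 0.09 on the log2(value + 1) scale (SE; limma adjusted p = 3.9e-08). DMBT1, a scavenger receptor glycoprotein of mucosal surfaces, fell from 10.0 ± 2.69 to 0.350 ± 0.223, which was 3.49% of the vector level (-3.02 ± 0.20, SE). TGFBI, a matrix protein induced by TGF-beta (chromosome 5, 136028895 to 136063818, plus strand), fell from 92.7 ± 1.33 to 10.7 ± 0.801, or -3.01 ± 0.06 (limma adjusted p = 7.4e-09). SERPINE2, a secreted inhibitor of thrombin and urokinase, fell from 161 ± 2.40 to 36.9 ± 1.48 (-2.09 ± 0.04, SE). F3 encodes tissue factor, the initiator of coagulation, and fell from 63.7 ± 4.49 to 8.92 ± 1.14. The phosphatase gene DUSP4 dropped from 9.16 ± 0.165 to 0.767 ± 0.0961 and the transglutaminase gene TGM2 from 14.1 ± 0.756 to 2.49 ± 0.410. EPGN, a ligand of the EGF receptor, fell from 21.9 ± 3.63 to 4.78 ± 2.23, and ANGPTL4, an inhibitor of lipoprotein lipase, from 11.5 ± 1.24 to 2.33 ± 0.528. With VPS35 as the tenth, the limma log2 differences of these genes ran from -3.24 to -1.92.

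The genes that rose most by the same rule included the secreted proteoglycan gene MAMDC2 (chromosome 9, 70043581 to 70226970, plus strand), which went from 4.22 ± 0.248 to 24.6 ± 1.48 (SD, n = 3 per group; log2 difference 2.29 ± 0.08, SE, limma adjusted p = 8.7e-08). Transcription factor genes were represented by ATOH8, a basic helix-loop-helix factor that rose from 4.30 ± 0.414 to 18.5 ± 2.69, and the homeobox gene DLX3, which rose from 1.23 ± 0.380 to 7.0 ± 0.660. RHOU, which encodes an atypical small GTPase, rose from 10.6 ± 0.210 to 37.6 ± 1.52. MRC2, an endocytic receptor for collagen, went from 9.86 ± 0.910 to 33.7 ± 1.37, and PKDCC, a secreted tyrosine kinase, from 6.02 ± 0.821 to 19.2 ± 2.36. SAMD11 rose from 5.09 ± 0.588 to 21.8 ± 3.71 and CTTNBP2, which encodes a cortactin-binding protein, from 0.720 ± 0.145 to 5.42 ± 0.561. AC016739.1, a processed pseudogene of a ribosomal protein gene, had 2.31 ± 2.12 in vector and 13.5 ± 5.76 in shVPS35 cells (log2 difference 2.35 ± 0.65, limma adjusted p = 0.0113). Its level is uncertain because reads can be shared with the parent gene, and with a pseudocount of 0.1 its limma adjusted p was 0.0574.

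AL355075.4 had the highest mean level of all listed genes. It rose from 402 ± 11 to 1500 ± 138 (SD, n = 3 per group), a log2 difference of 1.89 ± 0.07 (SE; limma adjusted p = 8.4e-08). The authors' deposited table describes this gene as ribonuclease P RNA component H1. GENCODE 29 instead places an antisense RNA gene under its identifier at chromosome 14, 20343048 to 20343685 on the minus strand, and it contains RPPH1, the RNA component of ribonuclease P, at 20343075 to 20343407 on the same strand. Reads of the overlapping genes cannot be separated in these values. Next in level came AKR1B1, the aldose reductase gene, which fell from 724 ± 21.2 to 390 ± 16.2 (-0.89 ± 0.04, SE). HPD encodes hydroxyphenylpyruvate dioxygenase of tyrosine breakdown and rose from 179 ± 4.03 to 381 ± 1.01. It was followed in mean level by SPINK6 and CDKN1A. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell from 234 ± 3.42 to 90.0 ± 5.88.

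Of the 24 MAPK feedback and immediate early genes, 10 were listed and all 10 fell, while 14 were not listed. The 14 included EGR1, FOS, FOSB, JUN, IER2, MYC and DUSP6. The 10 were CCND1, DUSP4, DUSP5, ETV4, ETV5, FOSL1, IER3, PHLDA1, SPRY2 and SPRY4. CCND1, which encodes cyclin D1 (chromosome 11, 69641087 to 69654474, plus strand), fell from 59.0 ± 1.40 to 16.9 ± 0.485 (SD, n = 3 per group; log2 difference -1.75 ± 0.05, SE, limma adjusted p = 3.9e-08). IER3, an immediate early gene, fell from 72.6 ± 3.32 to 22.1 ± 2.25, and ETV5, an ETS family transcription factor gene, from 24.7 ± 1.31 to 9.82 ± 0.363. The exact 2-sided binomial test against the up share of all listed genes (44.6%) gave p = 0.00303 for the direction of the 10, or 0.0303 after Benjamini-Hochberg adjustment over 10 lists. With only the 8 members whose higher group mean was at least 5, all of which fell, the adjusted p was 0.0913. Listed genes were also over-represented on this list in a hypergeometric test added after the data were seen (10 listed against 0.636 expected among 16063 tested genes, adjusted p = 4.1e-09).

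**Figure D2:**
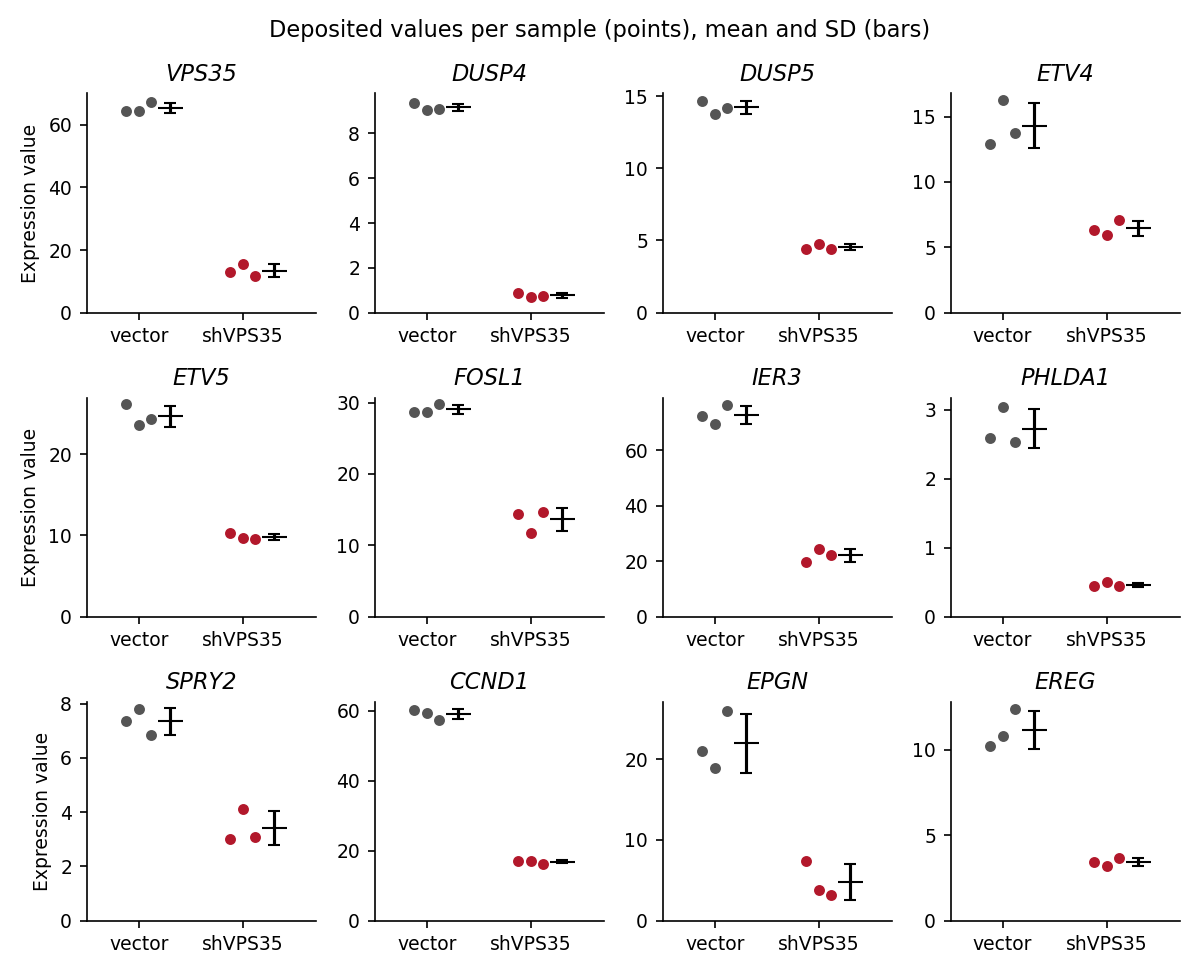
Expression values per sample (points, unit not named) in vector and shVPS35 cells for VPS35, 9 genes of the MAPK list and the EGF receptor ligands EPGN and EREG, with the mean and SD of the 3 samples as bars; EREG was chosen after its values were seen. In each panel all 3 shVPS35 samples lie below the 3 vector samples, as for CCND1 with means of 16.9 and 59.0.

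All 7 listed genes of the 26 on the NF-kB list fell, namely BIRC3, CXCL2, CXCL8, ICAM1, IL1A, IL1B and RELB. BIRC3, an inhibitor of apoptosis, fell from 45.9 ± 4.61 to 16.0 ± 1.98 (SD, n = 3 per group), and the adhesion receptor gene ICAM1 from 14.5 ± 1.82 to 6.96 ± 0.917. RELB, which encodes an NF-kB subunit, fell from 5.78 ± 0.563 to 2.48 ± 0.618, and the cytokine gene IL1A from 1.28 ± 0.0737 to 0.180 ± 0.106. The direction of the 7 did not pass the exact binomial test after adjustment (p = 0.0195, adjusted p = 0.0976). With only the 3 members whose higher group mean was at least 5, all of which fell, the adjusted p of that test was 0.524. The 7 listed did exceed the 0.690 expected among all genes tested (hypergeometric adjusted p = 3.5e-05). From the list of IL6, JAK and STAT3 signalling, with 26 members, only the oncostatin M receptor gene OSMR was listed, and it fell from 72.4 ± 0.280 to 40.9 ± 2.96. The 40 interferon-stimulated genes had 2 listed members, OAS2 and SAMD9L, and both fell (adjusted p = 0.723 for direction, exact binomial test).

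Genes of the epithelial to mesenchymal transition moved both ways. Of the 30 on the list, 6 were listed, of which 4 fell, TGFBI, CLDN1 and CDH2 among them, and 2 rose, SNAI2 and TWIST1. CLDN1, a tight junction protein gene, fell from 13.2 ± 0.499 to 3.29 ± 0.299 and CDH2, which encodes N-cadherin, from 37.4 ± 0.572 to 19.4 ± 0.754 (SD, n = 3 per group). SNAI2, the gene of the transcriptional repressor SLUG, rose from 3.91 ± 0.743 to 10.5 ± 0.623. Their direction did not pass the test (exact binomial adjusted p = 0.776), and their number was above that expected (hypergeometric adjusted p = 7.4e-04). The list mixes epithelial with mesenchymal genes, so a count of rises and falls cannot show the direction of a transition. Among 34 integrin and focal adhesion genes, ITGA2, ITGB4 and ITGB6 fell. ITGA2 went from 8.02 ± 0.310 to 2.84 ± 0.125 and ITGB4 from 12 ± 1.72 to 4.02 ± 0.503. ITGB6 had 1.71 ± 0.272 and 0.947 ± 0.415 (log2 difference -0.49 ± 0.17, SE, limma adjusted p = 0.0197). Its log2 fold change in the authors' deposited table, -1.62, is larger in size than the means give. The limma call for ITGB6 ended with trimmed-mean scaling and when vector sample 1 or shVPS35 sample 2 was left out (limma adjusted p = 0.0880, 0.0559 and 0.0606). Of 22 YAP and TAZ target genes, ANKRD1, F3 and NT5E fell, the last, which encodes the ecto-nucleotidase CD73, from 20.4 ± 2.07 to 6.69 ± 1.57. Neither the integrin nor the YAP and TAZ list passed the direction test (exact binomial adjusted p = 0.431 for each) or the over-representation test (hypergeometric adjusted p = 0.128 and 0.0532).

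CDKN1A, GDF15 and PLK3 were the listed members of 24 p53 target genes, and all 3 fell. GDF15, a stress-induced cytokine gene, went from 66.4 ± 2.17 to 28.6 ± 3.02 and the kinase gene PLK3 from 7.42 ± 1.21 to 3.68 ± 0.405 (SD, n = 3 per group). This list passed neither test (exact binomial adjusted p = 0.431, hypergeometric adjusted p = 0.0589). Of 40 proliferation and cell cycle genes, CCND1 alone was listed. The 22 Wnt target genes had 5 listed members, of which CCND1, NKD2 and EPHB2 fell and BAMBI and NOTUM rose. BAMBI, which encodes a decoy receptor for TGF-beta family ligands, rose from 8.08 ± 0.240 to 19.1 ± 0.852, and NOTUM, a secreted Wnt-inactivating enzyme gene, from 2.13 ± 0.0800 to 5.62 ± 0.111. NKD2, an antagonist of Wnt signalling, fell from 1.47 ± 0.320 to 0.573 ± 0.0764. Direction was mixed for the Wnt genes (exact binomial adjusted p = 1.0), and their number was above that expected (hypergeometric adjusted p = 0.0011).

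Epithelial markers of stomach and intestine fell where listed. From a list of 34, PSCA, a surface antigen of gastric epithelium, fell from 160 ± 7.19 to 69.7 ± 3.13, and the gastrokine genes GKN1 and GKN2 fell from 4.42 ± 0.0551 to 0.810 ± 0.144 and from 6.37 ± 0.562 to 2.14 ± 0.746 (SD, n = 3 per group). The mucin gene MUC13 fell from 15.5 ± 0.524 to 7.28 ± 0.312. The adjusted p was 0.431 for their direction (exact binomial test) and 0.0382 for their number (hypergeometric test), and 0.174 for their number against a background of 10000 genes. Markers of other cell types were checked beside them, and 4 of 21 were listed. CD68, a glycoprotein of lysosomes and endosomes used as a macrophage marker, fell from 55.6 ± 1.33 to 16.9 ± 0.369. The endothelial cadherin gene CDH5 had 0.980 ± 0.234 and 0.547 ± 0.121. Of the fibroblast proteoglycan genes, LUM had 1.17 ± 0.429 and 0.560 ± 0.373, and DCN rose from 1.48 ± 0.485 to 4.19 ± 1.22. For these markers the adjusted p was 0.776 for direction (exact binomial test) and 0.00775 for number (hypergeometric test).

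**Figure D3:**
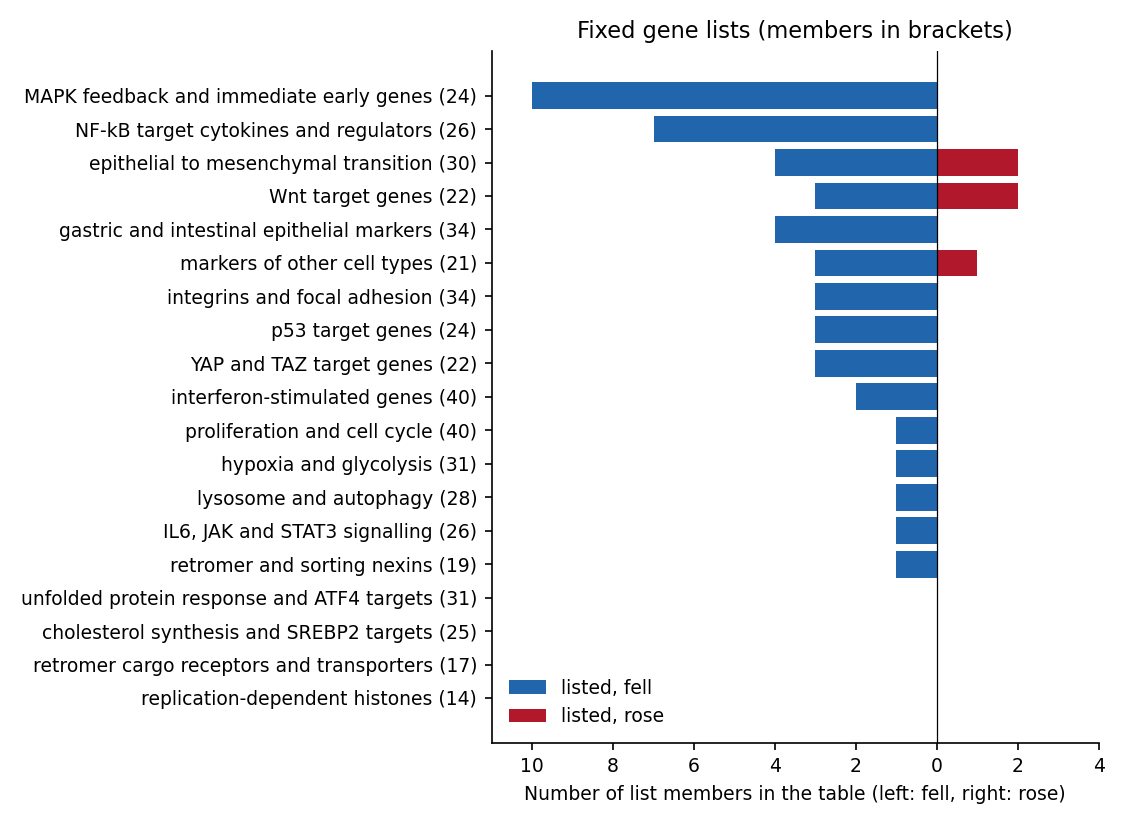
Bars give the number of members of each of the 19 gene lists (members in brackets) that the authors' deposited table lists as fallen (blue, left) or risen (red, right) in shVPS35 cells. The MAPK list has the longest bar, with 10 genes that fell and 0 that rose.

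Other lists that bear on endosomes and cell stress had few or no listed members. From 28 lysosome and autophagy genes the protease gene CTSS alone was listed, at 0.357 ± 0.153 in vector and 0.213 ± 0.201 in shVPS35 cells (SD, n = 3 per group). Its log2 fold change in the authors' deposited table, -2.37, is larger in size than these means give. Of 31 hypoxia and glycolysis genes, ADM, which encodes the vasodilator peptide adrenomedullin, fell from 62.2 ± 3.27 to 30.8 ± 2.81. None of the 17 retromer cargo receptors and transporters, the 25 cholesterol synthesis genes, the 31 genes of the unfolded protein response and ATF4, or the 14 replication-dependent histone genes was listed. A gene outside the list either missed a limit of the authors or was not tested, and its level is not analysed here. Each gene list also holds only part of the genes of its process, so a low count does not exclude changes in other such genes. CD68, the glycoprotein of lysosomes and endosomes that fell, is not on the lysosome list.

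The limma test covered the 292 listed genes with a value of 1 or more in at least 3 samples, and all 292 passed at an adjusted p of 0.05, 160 lower and 132 higher in shVPS35 cells. In every gene list the count of tested members that passed, adjusted over the list alone, equalled that adjusted over all 292 genes, for example 9 of 9 for the MAPK list. This equality was fixed in advance, because all 292 had already passed, and is no further check. Because the table holds only genes already called on these samples, the limma adjusted p-values are not independent evidence of change. They set each group difference against the spread between samples. An exact permutation test of 3 against 3 samples cannot give a p below 0.1. Genes of a list are co-regulated, so the binomial and hypergeometric p-values are too small to the extent that they move together, and a single knockdown group cannot separate loss of VPS35 from other effects of the hairpin RNA.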

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

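The over-representation tests were chosen only after the data were seen. The count of called genes was 292 and lay between 284 and 292 with pseudocounts of 0.1 and 5, centring on the median gene and trimmed-mean scaling. It was 279 at an adjusted p of 0.01, 408 with no filter, and 285 to 288 with each sample left out in turn. It fell to 140 with a filter of 5, which left 141 genes to test, and to 161 when an absolute log2 difference of 1 was also required. With a replicate block 291 genes were called, and samples with the same number did not deviate together (r = -0.06, -0.09 and 0.03 across genes), so the numbers do not pair them. VPS35 was lower under each alternative that was run, by -2.31 to -1.94 on the log2 scale. Scaling moved the median log2 difference of the tested genes by 0.09 (median gene) and 0.19 (trimmed mean). Both scalings were computed from listed genes only, which were chosen for a change. They therefore cannot measure a difference in scale between the libraries. Of 619 alternative values for the 48 named genes, 615 kept their direction and their side of the threshold, 4 lost the call and 0 reversed. The 4 belonged to AC016739.1 (pseudocount 0.1) and ITGB6 (trimmed-mean scaling, without vector sample 1, without shVPS35 sample 2), and the cause was not tested. The named genes had all passed in the main fit, and the listed genes were chosen for a difference between these 6 samples. The high share kept, and the counts with a sample left out, therefore follow largely from that choice. The direction test called 1 gene list, and 0 when only members with a higher mean of at least 5 were counted, where fewer genes entered (MAPK list, 8 of 8 fell, adjusted p = 0.0913, exact binomial test; range over its alternatives 0.0294 to 0.0913). It called 1 with each sample left out. Which genes were listed still rested on all 6 samples there, so this is no check on any single sample. Over-representation called 6 lists against all genes tested and 5 against 10000. Count-based alternatives and those that model correlation between genes were not run, since the values are not counts and a table of called genes gives no background. Unknown depth limits what can be said of the 134 listed genes below the filter.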

Other observations

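The genes and gene groups of the next 2 paragraphs were chosen after their values were seen, as were the tests of a scaling difference, of a single library and of protein-coding neighbours alone. The other tests of this part were set out before they were run. Some patterns that they address, such as the rise of AL355075.4, had been seen by then.

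Of 11 genes for ligands of the EGF receptor family, 6 were listed, and EPGN, EREG, AREG, TGFA, NRG1 and EGF each fell. The group was picked because its members fell, so a test of its direction would only restate that choice. TGFA fell from 8.51 ± 0.535 to 2.43 ± 0.841 (SD, n = 3 per group) and EREG from 11.1 ± 1.11 to 3.44 ± 0.216. AREG fell from 3.62 ± 1.01 to 1.69 ± 0.401 and NRG1 from 6.49 ± 1.48 to 2.10 ± 0.465. EGF was low throughout, at 0.407 ± 0.170 and 0.117 ± 0.0737. EPGN, EREG and AREG are neighbours on chromosome 4.

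Some single transcription factor genes rose and are named for that reason, while others fell, such as RUNX2 with a log2 fold change of -2.44 in the authors' deposited table. TBX1 rose from 5.04 ± 0.516 to 16.1 ± 2.03 (SD, n = 3 per group), DLX2 from 1.28 ± 0.188 to 5.32 ± 0.220 and DLX4 from 3.24 ± 0.491 to 9.06 ± 1.02. FOXF1 rose from 1.22 ± 0.0954 to 3.05 ± 0.141 and SIX2 from 0.563 ± 0.0907 to 1.68 ± 0.110. HOXD11, FOXN4, FOXC2 and MEOX1 rose in the authors' deposited table from low levels, with both group means below 1.

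The 292 calls between the groups compare with 0 as the highest count from any other split of the 6 samples into 3 and 3. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The genes were listed because they differed under the real split, so this count says nothing on chance.

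All 10 listed MAPK genes fell. A difference in scaling between the groups is argued against only as the whole cause of this fall. The median log2 fold change of these genes in the authors' deposited table was -1.64. A shift as large as that would have put most tested genes on the list, and 2.65% were listed. A smaller shift that carried some falls past the authors' limit is not excluded, since scale cannot be measured from listed genes. An off-target effect of the hairpin stays open, because the design has 1 knockdown group, whether its samples share a hairpin or clone is not given in the sources used here, and so the fall cannot be told apart from such an effect. An effect of VPS35 depletion stays among the open explanations, as untested.

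AL355075.4, whose span contains the ribonuclease P RNA, rose in all 3 shVPS35 samples. A single deviating library is argued against, as the lowest shVPS35 value was 3.26 times the highest vector value. More carry-over of RNAs without a poly(A) tail in the shVPS35 libraries could also raise it, and this cannot be told apart from a change in the cells. The 1 listed gene counted in the non-polyadenylated classes is AL355075.4 itself, for the ribonuclease P RNA in its span. No other listed gene could therefore show such carry-over. None of the 14 replication-dependent histone genes, whose RNAs lack a poly(A) tail, was listed, but whether they were among the genes tested is unknown. A response of this RNA to VPS35 depletion stays among the open explanations, as untested.

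Fold changes in the authors' deposited table differ from the ratios of the deposited sample values for some genes. In the authors' deposited table the log2 fold change was 3.81 for CHML and -3.11 for NAV3, against 1.49 and -1.62 from the deposited means, and ADAMTS4 and NIPAL1 have opposite signs (1.59 against -0.24, and -1.33 against 0.69). ADAMTS4 (0.193 ± 0.266 in vector, 0.163 ± 0.0603 in shVPS35 samples; SD, n = 3 per group) and NIPAL1 (0.553 ± 0.0513 and 0.893 ± 0.936) are low and their groups overlap, so the sign of their deposited means is within the spread. Of the 423 genes with both means above 0, 13 differed by more than 1 on the log2 scale, and 2 of those with both means of 1 or more did. In the 80 genes with both means of 5 or more the difference was small (median 0.03, range -0.34 to 0.40). Rounding to 2 decimals is argued against as the whole cause, since 11.9% of the 270 genes with both means of 0.5 or more lay over 0.3 outside the range that rounding allows. Reads moving between isoforms of different length are a candidate explanation. For genes with both means of 1 or more, differences were centred on their median before their absolute size was taken. The median size was larger in 92 genes with more than 6 annotated transcripts (0.0829) than in 103 with 6 or fewer (0.0237, 1-sided permutation p = 2.0e-05), which goes with that explanation. CHML, with the largest gap named here, goes against the isoform explanation with 5 annotated transcripts, and NAV3 has 16. The low genes ADAMTS4 and NIPAL1 have 3 and 6.

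Of 46 non-overlapping pairs of listed neighbours within 200 kb, 35 (76.1%) had the same direction, against a mean of 50.5% over 10000 reshuffles (permutation p = 5.0e-04), while among the 26 protein-coding pairs of different families 17 did (permutation p = 0.101). Directions by chromosome gave a chi-square of 22.6 against a mean of 22.1 over reshuffles (permutation p = 0.429), which does not decide on a difference in chromosome copy number between the cells.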
